A study of Mus musculus with 9 samples.

How the data were processed

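The measurement was poly(A) RNA abundance in whole mouse embryos. Each of 9 libraries was made from a pool of 3 embryos taken at 34 h after fertilization, and the labels place 3 libraries, named A, B and C, in each of 3 groups. SPN received a sham transfer and served as control, EPN received early pronuclear transfer and LPN received it later. Per the labels, cDNA was made with the Smart-seq2 v4 kit and libraries with Nextera XT, and 150-bp paired ends were read on a NovaSeq instrument. The labels do not say whether the pools came from separate days, matings or operators, so p-values measure only the spread between these libraries.

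Per the submitters' processing notes, Trim Galore 0.6.7, HISAT2 2.2.1, R 3.3.3 and edgeR were used with the GRCm39 assembly. The read counter, the gene annotation and the test used by the authors were not given in the sources used here. The authors deposited CPM, the reads of a gene scaled to a common library total, for 19359 genes, with 1 column for each of the 9 libraries. In every library 100% of the deposited CPM values were whole multiples of 1 step within a tolerance of 0.01 reads, which gave back whole reads and the library total used as divisor, with no further scaling factor. These totals ran from 7611781 to 15559218 reads, and 3.66% to 5.68% of each total lay outside the table and was not analysed here. Whether these reads belong to genes is not stated. A single read equalled 0.0643 to 0.131 CPM, and a count of 0 allowed up to 3 reads, or 0.193 to 0.394 CPM in a library. Such limits cover counting error only, since reads without molecular identifiers are not independent molecules.

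Gene symbols were used as deposited. The available mouse annotation covers an older assembly than the one used by the authors, so no coordinates are given; 19157 of the 19359 symbols occur in it. Among tested genes, 67 sets holding 136 genes had identical values in every library and count as repeats of each other. Reads of multi-copy families (Zscan4, Usp17l, Eif1ad, Tdpoz, Tcstv) can map to several members, so the split between members of a family is uncertain.

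The choices described next were made before the data were examined. Genes with at least 1 CPM in at least 3 of the 9 libraries were tested, 14876 in all. Values were log2(CPM + 1), as deposited, because the rule set rescaling by median-of-ratios only where every column summed to the full CPM scale, and none did. One limma model (limma 3.58.1 in R 4.3.3; trend-adjusted empirical Bayes, 6 residual and 25.9 prior degrees of freedom) gave 3 two-sided contrasts and an F test over the 3 groups. P-values were adjusted by the Benjamini-Hochberg method within each contrast, and a call is an adjusted p under 0.05. Fold changes are on the log2(CPM + 1) scale and are therefore drawn towards 1 for genes of low CPM. Each ± after a CPM value is the SD of 3 libraries, and each SE is the standard error of the limma contrast.

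There were 30 gene lists, fixed in advance, with members counted where tested. They covered minor zygotic genome activation (2-cell-specific) genes, preimplantation transcription factors, oocyte-derived transcripts, maternal mRNA clearance machinery, p53 targets, DNA damage response and repair, DNA replication, mitosis and cell cycle, nucleolus and ribosome biogenesis, and cytosolic ribosomal proteins. Others were mitochondrially encoded genes, nuclear oxidative phosphorylation genes, mitochondrial ribosomal proteins, mitochondrial dynamics, proteasome subunits, splicing factors, heat shock and protein folding, unfolded protein and integrated stress response, oxidative stress response, apoptosis, and chromatin and DNA methylation enzymes. The rest were histone chaperones, imprinted genes, interferon-stimulated genes, cytoskeleton and cell adhesion, blastocyst lineage markers, Y-linked genes, and markers of cumulus and granulosa cells, sperm and blood. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the 30 lists within a comparison. Summed list CPM and library measures were compared by two-sided exact permutation tests, whose smallest possible p with 3 against 3 libraries is 0.1.

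Genes were named by a rule. In each comparison it took the called genes with a mean of at least 5 CPM, groups that did not overlap and a symbol that is not a predicted or clone name, up to 8 with the largest change each way. It added up to 4 called members of each list by smallest adjusted p, or up to 2 by smallest p where no member was called. It also took Zscan4d, Zfp352, Gdf9, Zp3, Cdkn1a, Mdm2, Pcna, Npm1, Pou5f1 and COX1 everywhere. A few genes outside the rule are named as such.

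The pipeline was tested on simulated data, 3 sets per comparison with 100 genes changed at each fold size. For EPN against SPN it recovered 36.7% of the 4-fold changes and 4% of the 2-fold changes. The shares were 37.7% and 5.7% for LPN against SPN, and 32% and 3.7% for LPN against EPN. Unchanged genes made up 5.4%, 7.1% and 4.5% of these calls, in the same order. The simulated genes were drawn independently, with no correlation between genes and no deviating library, so these shares need not hold for the real data.

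Alternatives were a pseudocount of 0.1 or 5 CPM, no filter, a mean of at least 5 CPM, median-of-ratios scaling, quantile normalization, a fit on the 6 libraries of a pair, array quality weights, a replicate block, a required log2 fold change of at least 1, and leaving out each library in turn. On the recovered reads, edgeR 4.0.16 (quasi-likelihood test with TMM factors) and DESeq2 1.42.0 were run as well. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.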

Results

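The data are 9 transcriptomes of mouse embryos pooled by 3 and taken at 34 h after fertilization, with 3 libraries for each of the sham (SPN), early (EPN) and later (LPN) pronuclear transfer groups. Pronuclear transfer moves the pronuclei of a zygote into another cytoplast, and the labels give the timing of the procedure as the variable, with SPN as control. Library totals in the order A, B and C were 13960413, 11287155 and 11429756 reads in SPN, 13835748, 12800543 and 13348983 reads in EPN, and 15559218, 7611781 and 11936503 reads in LPN. A mean of 13555 ± 427 genes in SPN, 13446 ± 491 in EPN and 13187 ± 595 in LPN reached 1 CPM (SD, n = 3; exact permutation p = 0.5 for each pair of groups).

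The first principal component carried 30.5% of the variance and the next one 15.7%. The LPN libraries lay at the positive end of the first component, from 36.8 to 77.9, and SPN B and SPN C at the negative end, at -50.6 and -84.6. SPN A, at -2.0, lay beside the EPN libraries, which ran from -29.4 to 7.3. Its mean Spearman correlation across genes was 0.916 with the EPN libraries and 0.897 with the other SPN libraries; genes are not independent replicates, so these describe resemblance only.

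**Figure D1:**
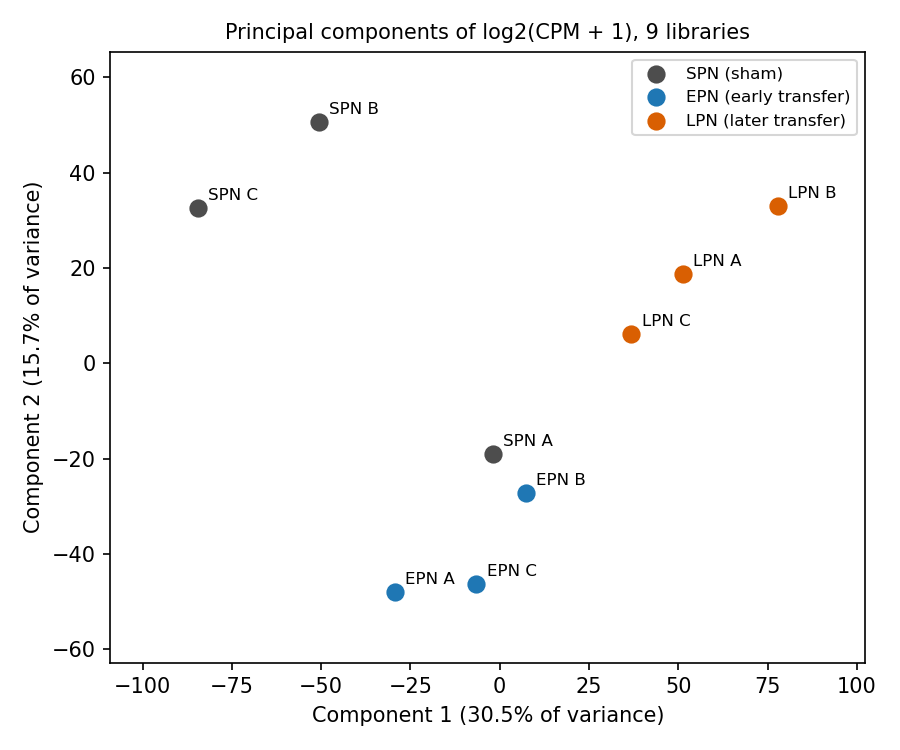
Principal components of log2(CPM + 1) for the 9 libraries; each point is 1 library, coloured by group, and the axes give component scores with 30.5% and 15.7% of the variance. LPN libraries lie from 36.8 to 77.9 on the first component, and SPN A, at -2.0, lies among the EPN libraries.

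Across the 3 groups, 852 of 14876 tested genes were called by the F test, with 3768 at an unadjusted p under 0.05. On the recovered reads edgeR called 107 and DESeq2 1862. The count was 2565 without SPN A, 419 without SPN B, 191 without SPN C, 518 without EPN A, 478 without EPN C, 287 without LPN A and 63 without LPN B. The median of all genes lay at -0.07 log2 in EPN against SPN, -0.17 in LPN against SPN and -0.14 in LPN against EPN, and list medians below are given relative to it. Median-of-ratios scaling brought these shifts to -0.02, -0.03 and -0.04.

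Early transfer was compared with the sham procedure to ask which transcripts differ when pronuclei are moved early. The clearest differences were in single genes. Calhm3, a calcium homeostasis modulator channel subunit, rose 8.42-fold, from 13.1 ± 15.5 CPM in SPN to 80.1 ± 23.7 CPM in EPN (SD, n = 3; log2 change 3.07, SE 0.48, limma adjusted p = 0.00495). Ciart, a repressor of circadian transcription, rose 5.63-fold, from 16.2 ± 7.95 to 93.2 ± 30.7 CPM (adjusted p = 0.00571), and Efna1, an ephrin ligand, rose 4.2-fold, from 50.5 ± 27.3 to 195 ± 19.2 CPM (adjusted p = 0.00662). Spp1, which encodes osteopontin, rose 10.8-fold from 2.48 ± 3.09 to 28.2 ± 10.4 CPM (adjusted p = 0.0368). Iqub, an IQ-motif and ubiquitin-domain gene, fell 3.61-fold, from 91.7 ± 14.7 to 24.6 ± 2.8 CPM (adjusted p = 0.0199).

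In all, 16 genes were called in EPN against SPN, 11 higher and 5 lower in EPN, and 1643 had an unadjusted p under 0.05. The groups of all 16 called genes did not overlap, as in 14.6% of all tested genes, where chance gives 10%. Bex1, the multi-copy gene Tdpoz8, the lysosomal protease gene Ctsc and the splicing factor gene Srsf5 rose between 2.77-fold and 3.76-fold. The clathrin adaptor gene Clint1 fell 7.55-fold, the Rac exchange factor gene Prex2 3.36-fold and Ankrd22 2.99-fold. SPN A had 15.5 CPM of Clint1, against 181 and 173 CPM in SPN B and SPN C and 6.8 to 13 CPM in EPN. The fifth gene that fell, named after its values were seen because the naming rule excluded it for its low mean, was the stem cell factor gene Utf1, with 12.1 ± 6.32 CPM in SPN and no read in EPN.

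Among the gene groups, the 2-cell-specific genes, which are transcribed in the earliest wave of embryonic transcription, had the largest positive median in EPN against SPN. It was 0.75 log2 above that of all genes and 34 of 40 members had a positive difference. The camera test called the list (adjusted p = 9.05e-13), and this call was lost (adjusted p = 0.624 with an estimated correlation). No member passed over all genes, and adjusted over the list alone 15 rose and 1 fell. The multi-copy members Usp17lb (607 ± 400 to 1464 ± 83.6 CPM) and Eif1ad7 (238 ± 37.3 to 562 ± 163 CPM) had the smallest p-values, with adjusted p = 0.0648 and 0.0858 over all genes. In SPN A the mean log2 value of this list was 6.76, against 6.49 and 6.1 in SPN B and SPN C and 6.95 to 7.38 in EPN.

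The camera test also called 2 further lists as higher in EPN. Nucleolus and ribosome biogenesis genes had a relative median of 0.27, with 70 of 100 members positive (adjusted p = 0.000172, and adjusted p = 0.82 with an estimated correlation). Histone chaperones and replacement histones had a relative median of 0.30, with 20 of 28 positive (adjusted p = 0.0137, and adjusted p = 0.624 with an estimated correlation). No member of either list passed over all genes; Ltv1 (146 ± 67.5 to 302 ± 53.6 CPM, adjusted p = 0.129) and Supt16 (20.5 ± 10.3 to 59.4 ± 12.7 CPM, adjusted p = 0.092) came closest, and adjusted over the list alone 1 histone chaperone rose. Both calls ended without SPN C, where the relative medians were 0.17 (adjusted p = 0.0967) and 0.22 (0.0972), and without EPN C, where they were 0.16 and 0.29 (0.0544 for both), with fewer samples in each case.

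The remaining 27 lists had no call in EPN against SPN. Oocyte-derived transcripts had a relative median of -0.08 (adjusted p = 0.175), and the lists of p53 targets (relative median 0.11, adjusted p = 0.65) and DNA damage response genes (-0.01, adjusted p = 0.701) lay close to all genes. Adjusted over the list alone, 1 oocyte gene fell, Oosp3 (349 ± 14.2 to 158 ± 10.1 CPM), and no p53 target or repair gene passed. The counts of EPN against SPN depended on single libraries: 458 genes were called without SPN A, 1 without SPN B, 3 without SPN C, 4 without EPN A, 9 without EPN B and 0 by limma without EPN C, where 1152 genes had an unadjusted p under 0.05. With edgeR the count was 0 (1342 at an unadjusted p under 0.05) and with DESeq2 142, while median-of-ratios scaling left 3 genes, all higher in EPN, and a pseudocount of 0.1 CPM left 4.

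Later transfer was compared with the same sham libraries to ask which transcripts differ when pronuclei are moved later. Of the oocyte-derived transcripts 16 of 65 fell and 2 rose, and 8 of 25 mRNA clearance genes fell, while 11 of 40 2-cell-specific genes, 8 of 37 proteasome subunits (with 1 that fell) and 9 of 100 ribosome biogenesis genes rose. The camera test called these 5 lists, and each call was lost with an estimated correlation (adjusted p = 0.355 to 0.563 with an estimated correlation). Bcl2l10, a BCL2 relative abundant in oocytes, fell 3.09-fold from 1573 ± 376 CPM in SPN to 512 ± 146 CPM in LPN (SD, n = 3; log2 change -1.63, SE 0.27, limma adjusted p = 0.00145). Eif1ad7, a multi-copy 2-cell gene, rose 3.38-fold from 238 ± 37.3 to 824 ± 227 CPM (log2 change 1.76, SE 0.28, adjusted p = 0.000985), and Psmd14, a deubiquitinase subunit of the proteasome lid, rose 2.9-fold from 126 ± 25.4 to 366 ± 65.9 CPM (adjusted p = 0.00293). Calhm3 rose 12.4-fold to 117 ± 26.1 CPM (adjusted p = 0.000184), and Vegfa, a vascular growth factor gene, fell 21.5-fold from 34.1 ± 20.2 to 0.578 ± 1.0 CPM (adjusted p = 0.000378). Vegfa had no read in LPN B and LPN C, so its fold depends on the pseudocount, with log2 changes from -6.78 to -2.65 over the alternatives.

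In total 1309 genes were called in LPN against SPN, 485 higher and 824 lower in LPN, with 4005 at an unadjusted p under 0.05; 1197 of them differed by at least 1 on the log2 scale. Groups did not overlap for 27.5% of tested genes, where chance gives 10%. Among the genes with the largest rises were Iqca1l (6.69-fold), the meiotic recombinase gene Dmc1 (7.16-fold), the RNA export factor gene Nxf2 (6.4-fold) and the growth factor gene Fgf7 (6.23-fold). Nxf2 was at 117 CPM in SPN A, 10 CPM in SPN B, 18.5 CPM in SPN C and 135 CPM in LPN A; its log2 change ran from 1.97 to 3.68 over the alternatives, and its call was lost with edgeR and DESeq2. Clint1 fell 11.3-fold and the transcription factor gene Gbx2 6.35-fold.

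**Figure D2:**
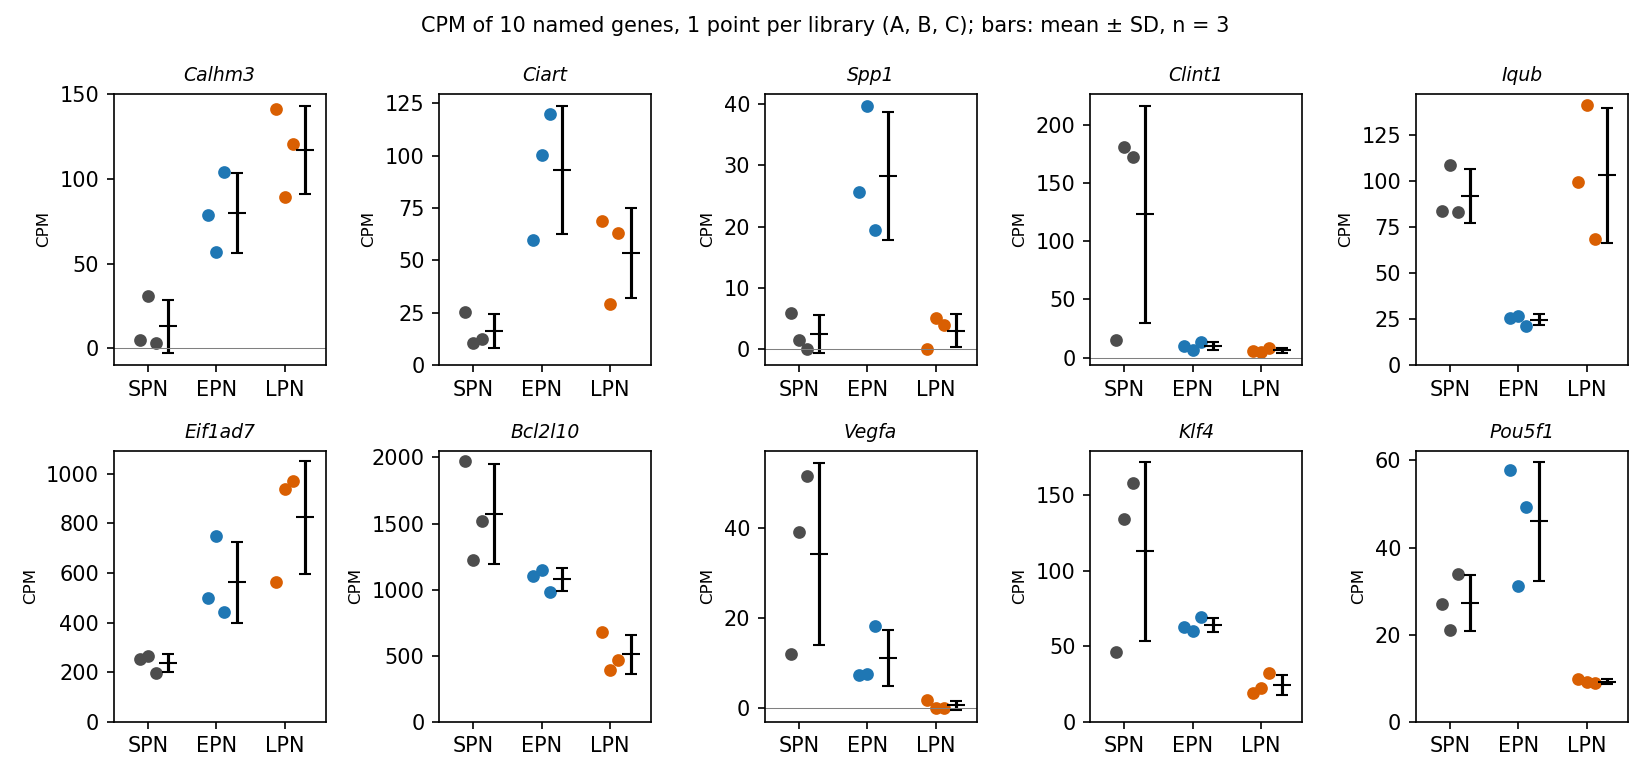
CPM of 10 named genes in the 3 groups; each point is 1 library (A, B, C from left to right), and bars show the mean ± SD of 3 libraries. Calhm3 and Eif1ad7 rose in LPN, reaching 117 and 824 CPM, while Bcl2l10, Vegfa, Klf4 and Pou5f1 fell; Clint1 in SPN A, at 15.5 CPM, lay apart from SPN B and SPN C.

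Of the 40 tested 2-cell-specific genes, 11 rose in LPN and 29 did not pass, with none lower among those that passed. The mean log2 value of the list was level in SPN A (6.76) and LPN A (6.77). The relative median was 0.88 (camera adjusted p = 2.81e-12, and adjusted p = 0.355 with an estimated correlation), and adjusted over the list alone 19 rose. Examples beside Eif1ad7 were Eif1ad3 (207 ± 58.2 to 643 ± 156 CPM), Tcstv3 (348 ± 57.8 to 942 ± 249 CPM), Usp17lb (607 ± 400 to 1741 ± 532 CPM) and Zfp352 (379 ± 156 to 812 ± 236 CPM, adjusted p = 0.0152). Zscan4d, at 369 ± 180 CPM in SPN and 706 ± 216 CPM in LPN, did not pass over all genes (adjusted p = 0.0593).

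Among 65 oocyte-derived transcripts, 16 fell, 2 rose and 47 did not pass (relative median -0.52; camera adjusted p = 1.22e-05, and adjusted p = 0.563 with an estimated correlation). Adjusted over the list alone 20 fell and 2 rose. Nlrp4f fell 2.76-fold, the deubiquitinase gene Uchl1 2.57-fold, Oosp3 2.62-fold and the oocyte growth factor gene Gdf9 2.53-fold. Zp3, which encodes a zona pellucida protein, rose 2.24-fold instead, from 86.6 ± 17.8 to 196 ± 43.9 CPM (adjusted p = 0.0166). The other oocyte gene that rose was Rfpl4b, named after its values were seen (log2 change 1.34, SE 0.32).

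Of 25 genes of the maternal mRNA clearance machinery, 8 fell, none rose and 17 did not pass. The relative median was -0.68 (camera adjusted p = 0.000393, and adjusted p = 0.355 with an estimated correlation). The fry test, which sets a list against no change and not against other genes, called this list (adjusted p = 0.032) and 0 of the other 29 in LPN against SPN, with 0.0522 for the proteasome, 0.077 for oocyte transcripts and 0.105 for 2-cell genes. It called 0 lists in EPN against SPN and in LPN against EPN (lowest adjusted p = 0.335 and 0.0989). These fry values are for CPM as deposited, where the median of all genes lay at -0.17 log2 in LPN against SPN. That shift counts towards lists that fall and against lists that rise. How the fry values change with other scaling was not examined. Adjusted over the list alone 15 fell and 1 rose. The decapping factor gene Dcp1a fell 3.62-fold, the deadenylase genes Cnot6l and Pan3 2.7-fold and 2.41-fold, and the m6A reader gene Ythdf3 2.52-fold. Summed CPM of the list was 5481 ± 1268 in SPN, 4861 ± 670 in EPN and 3593 ± 435 in LPN (SD, n = 3; exact permutation p = 0.1 for LPN against SPN, the smallest possible). With median-of-ratios scaling these sums were 5312 ± 1921, 4750 ± 288 and 3890 ± 729 CPM (exact permutation p = 0.5 for LPN against SPN), and LPN and SPN overlapped.

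Of 37 proteasome subunits 8 rose in LPN, 1 fell and 28 did not pass. Their relative median was 0.72 (camera adjusted p = 5.81e-07, and adjusted p = 0.355 with an estimated correlation), and adjusted over the list alone 16 rose and 1 fell. Psmd7 rose 2.23-fold and the ATPase subunit gene Psmc2 2.33-fold, while Psmd3, a lid subunit gene, fell 3.58-fold. Of 100 nucleolus and ribosome biogenesis genes 9 rose and none fell, also when adjusted over the list alone, with a relative median of 0.53 (camera adjusted p = 1.57e-06, and adjusted p = 0.551 with an estimated correlation). Dcaf13 rose 2.86-fold and Brix1, a factor of the large ribosomal subunit, 2.27-fold.

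**Figure D3:**
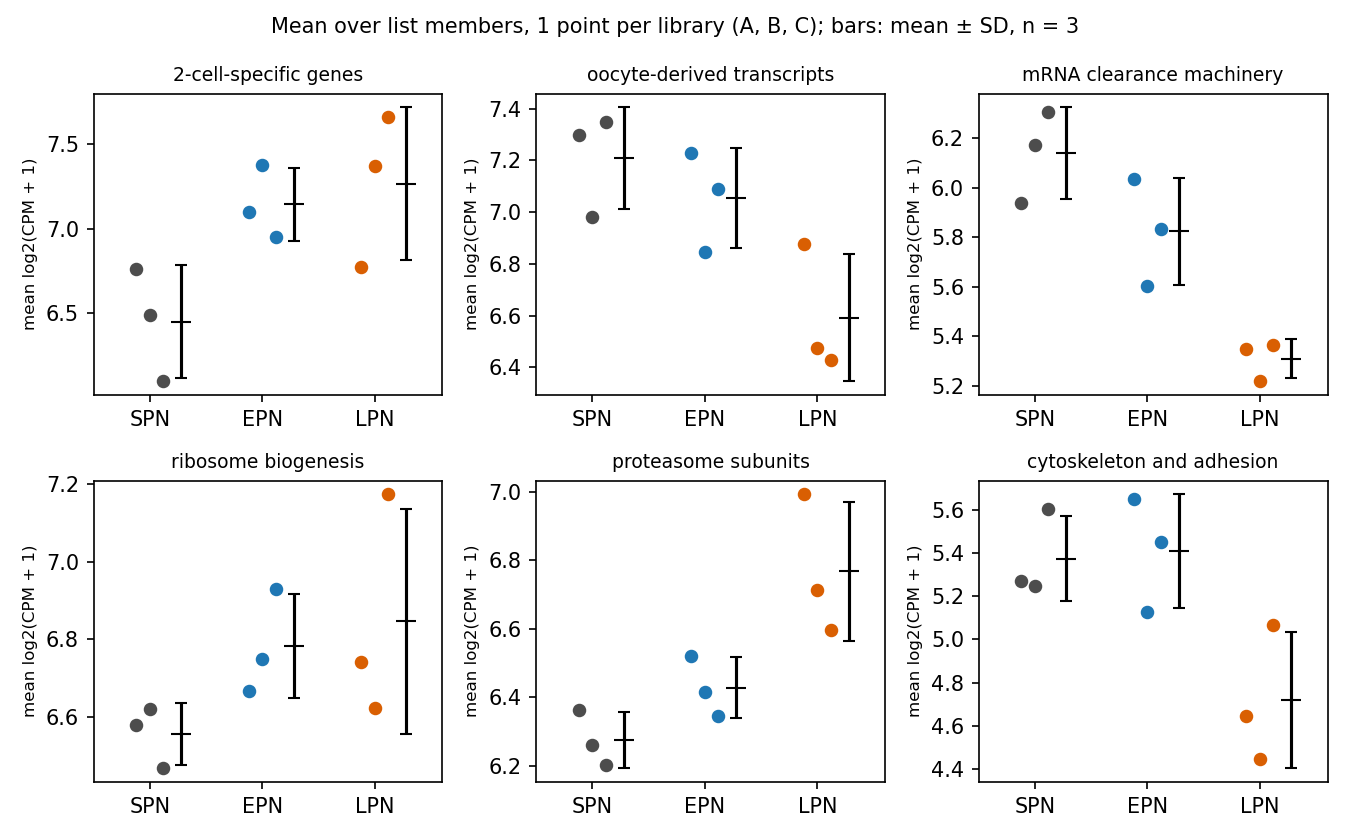
Mean log2(CPM + 1) over the tested members of 6 gene lists; each point is 1 library (A, B, C from left to right), and bars show the mean ± SD of 3 libraries. For the clearance machinery the LPN libraries lie from 5.22 to 5.36 and the SPN libraries from 5.94 to 6.31; for the proteasome they lie from 6.6 to 6.99 and from 6.2 to 6.36.

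DNA replication genes had 3 of 61 members higher in LPN and none lower, also adjusted over the list alone, with a relative median of 0.46 (camera adjusted p = 0.00174, and adjusted p = 0.355 with an estimated correlation). These were the origin recognition gene Orc3 (3.94-fold), the clamp loader gene Rfc2 (3.4-fold) and the primase gene Prim1 (2.1-fold). Pcna was at 217 ± 32.6 CPM in SPN and 266 ± 44.7 CPM in LPN (adjusted p = 0.52). Mitochondrial ribosomal proteins had 3 of 74 members higher, also adjusted over the list alone, and a relative median of 0.40 (camera adjusted p = 0.00197, and adjusted p = 0.563 with an estimated correlation; adjusted p = 0.109 without LPN A). Mrps10 rose 4.78-fold, from 12.5 ± 7.91 to 57.1 ± 8.79 CPM. Over all tested genes 485 of 14876 were higher and 824 lower in LPN. The 3 of 61 and 3 of 74 lie near the first share, and counts of falling members below should be read beside the second.

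Cytosolic ribosomal proteins, with 1 of 89 members higher, and nuclear oxidative phosphorylation genes, with 2 of 79 higher and 1 lower, had relative medians of 0.31 and 0.29. Adjusted over the list alone no member of either passed. Their camera adjusted p was 0.0199 and 0.0474, and adjusted p = 0.772 with an estimated correlation for both. Without SPN A these became 0.469 and 0.302, and for oxidative phosphorylation 0.183 without LPN A and 0.0649 without LPN B. Quantile normalization and array quality weights also ended the call of the cytosolic ribosomal proteins (relative medians 0.05 and 0.12). The oxidative phosphorylation call ended with these settings (0.23 and 0.26), with a mean of at least 5 CPM (0.24) and with a fit of the 6 libraries (0.30). Rpl6 and Ndufa9 rose 1.83-fold and 1.97-fold, and Cox8a fell 1.94-fold.

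Cytoskeleton and adhesion genes had 7 of 36 members lower in LPN and none higher (relative median -0.45; camera adjusted p = 0.00312, and adjusted p = 0.563 with an estimated correlation), with 8 lower adjusted over the list alone. The tubulin gene Tuba1c fell 3.11-fold, the E-cadherin gene Cdh1 3.28-fold and the tight junction gene Tjp1 2.95-fold. Blastocyst lineage markers had 2 of 21 members lower, the keratin gene Krt8 (9.48 ± 5.47 to 0.257 ± 0.445 CPM) and Fabp5, with 3 lower adjusted over the list alone. Their relative median was -0.56 (camera adjusted p = 0.0096, adjusted p = 0.563 with an estimated correlation, and 0.0606 with a mean of at least 5 CPM). Among preimplantation transcription factors, a list without a call (adjusted p = 0.0825), Klf4 fell 4-fold, Klf5 2.55-fold and Yap1 2.34-fold, Pou5f1 fell from 27.3 ± 6.48 to 9.26 ± 0.506 CPM (adjusted p = 0.0314), and Prdm14 rose 4.21-fold. SPN A, at 97.7 CPM of Yap1, lay inside the LPN range of 70.2 to 120 CPM.

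Other lists without a call held genes that changed. Of 55 chromatin and DNA methylation enzymes 7 fell, including the demethylase gene Kdm1b (2.94-fold) and the dioxygenase gene Tet3 (2.6-fold), and 1 rose (relative median -0.24, adjusted p = 0.0827). Of 66 mitosis genes 5 rose and 5 fell (relative median 0.18, adjusted p = 0.171); the anaphase-promoting complex activator gene Fzr1 fell 5.39-fold and the central spindle gene Prc1 rose 3.26-fold. SPN A, at 703 CPM of Prc1, lay inside the LPN range of 632 to 855 CPM, and the call was lost without SPN B (log2 change 1.44), without SPN C (1.12), with edgeR (1.19) and with DESeq2 (1.23). Of 78 splicing factors 6 rose and 2 fell (relative median 0.25, adjusted p = 0.0836), and of 73 DNA damage response genes 3 rose and 2 fell (relative median 0.29, adjusted p = 0.061), with Parp2 (1.94-fold) among those that rose. No p53 target passed over all genes or over the list alone, with a relative median of -0.24 (adjusted p = 0.428). Cdkn1a was at 79.9 ± 43.5 CPM in SPN and 48.8 ± 12.0 CPM in LPN (adjusted p = 0.403), and Mdm2 at 113 ± 31.7 and 106 ± 17.8 CPM (adjusted p = 0.916).

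Smaller numbers passed in 8 further lists, none of which was called. Of 36 unfolded protein and integrated stress response genes 1 rose, the transcription factor gene Ddit3 (2.75-fold), and 2 fell (relative median -0.28, adjusted p = 0.438). Of 36 heat shock genes 1 rose and 3 fell, among them Hsf1 (2.64-fold), with a relative median of 0.10 (adjusted p = 0.974). Of 37 oxidative stress genes 1 rose and 2 fell (relative median -0.08, adjusted p = 0.469), and of 29 apoptosis genes 1 rose and 3 fell (relative median 0.43, adjusted p = 0.886). Of 32 mitochondrial dynamics genes 2 rose and 2 fell, with the fission factor gene Mff 3.54-fold lower (relative median 0.14, adjusted p = 0.886), and among 13 mitochondrially encoded genes ND6 fell 2.21-fold (relative median -0.04, adjusted p = 0.655), with SPN A (105 CPM) inside its LPN range of 65.7 to 119 CPM. Of 28 histone chaperones 2 rose and 1 fell (relative median 0.19, adjusted p = 0.469); Supt16 rose 3.38-fold. Of 28 imprinted genes 2 fell, Phlda2 (2.96-fold) and Plagl1 (3.45-fold), with a relative median of -0.43 (adjusted p = 0.0702).

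Direction counts in LPN against SPN moved with the scaling. Of the calls 37.1% were higher in LPN as deposited, against 55% of 1209 calls with median-of-ratios scaling and 49.9% of 1306 calls with quantile normalization. The count was 2753 without SPN A, 454 without SPN B, 123 without SPN C, 604 without LPN A and 321 without LPN B; edgeR called 454 and DESeq2 2012. Of the named genes with a call, 0 of 12 in EPN against SPN and 0 of 38 in LPN against EPN kept it under every alternative, and 20 of 99 in LPN against SPN, among them Calhm3, Vegfa, Clint1, Eif1ad7, Tcstv3, Bcl2l10, Psmd14, Psmd3, Fzr1, Mff, Phlda2 and Tuba1c. With no filter limma called 0 genes in EPN against SPN and in LPN against EPN, so no gene there could keep its call. SPN A lay nearer to the LPN mean than to that of SPN B and SPN C, on the log2 scale, for Clint1, Usp17lb, Zfp352, Klf4, Cnot6l, Pan3, Tet3 and Srsf5, among others. Of the 99, 53 kept the call with edgeR and 92 with DESeq2, 25 without SPN C, 47 without LPN B, 56 without SPN B, 63 without LPN A, 87 without LPN C and 97 without SPN A.

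The contrast of LPN with EPN asks which transcripts differ with the timing of the transfer, and it is also the test of whether the 2 differences from SPN are unequal. All embryos were taken at 34 h after fertilization, so a later transfer also left less time before collection. The contrast cannot tell these apart. Pou5f1, the pluripotency factor gene also known as Oct4, was at 46.1 ± 13.7 CPM in EPN and fell 4.45-fold to 9.26 ± 0.506 CPM in LPN (SD, n = 3; log2 change -2.15, SE 0.42, limma adjusted p = 0.0149). Tuba1c fell 3.54-fold from 196 ± 30.1 to 54.6 ± 5.38 CPM (adjusted p = 0.00569), and the glutathione peroxidase gene Gpx1 2.7-fold from 422 ± 81.6 to 154 ± 19.2 CPM (adjusted p = 0.0149). The mitochondrial transcription elongation factor gene Tefm rose 5.75-fold from 14.3 ± 5.61 to 86.2 ± 34.1 CPM (adjusted p = 0.00569), and the poly(ADP-ribose) polymerase gene Parp2 2.83-fold from 84.8 ± 12.9 to 245 ± 57.0 CPM (adjusted p = 0.0149).

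There were 228 calls, 103 higher and 125 lower in LPN, and 2872 genes had an unadjusted p under 0.05. Groups did not overlap for 26.6% of genes, where chance gives 10%. The largest rises included the acetylcholine receptor subunit gene Chrne (8.16-fold), the pancreatic lipase gene Pnlip (7.38-fold) and the gap junction gene Gja3 (6.05-fold). Spp1 fell 9.06-fold, to 2.99 ± 2.67 CPM, the asparagine synthetase gene Asns 8.34-fold and Vegfa 7.88-fold. Cdkn1a, at 158 ± 92.4 CPM in EPN and 48.8 ± 12.0 CPM in LPN, did not pass (adjusted p = 0.0528).

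The camera test called 14 of 30 lists, and 0 with an estimated correlation (lowest adjusted p = 0.558 with an estimated correlation). Over all 14876 tested genes 103 were higher and 125 lower in LPN, so 1 called member says little about its list. Lower in LPN than in EPN were oocyte-derived transcripts (relative median -0.33, 5 of 65 fell, adjusted p = 0.000149), the clearance machinery (-0.42, 1 of 25, adjusted p = 0.00727), cytoskeleton and adhesion genes (-0.56, 2 of 36, adjusted p = 6.55e-05) and blastocyst markers (-0.75, 1 of 21, adjusted p = 0.00727). So were preimplantation transcription factors (-0.28, 1 of 24, adjusted p = 0.0135), unfolded protein response genes (-0.35, 1 of 36, adjusted p = 0.00727) and chromatin enzymes (-0.32, 1 of 55, adjusted p = 0.0037). Adjusted over the list alone, 9 oocyte transcripts, 4 clearance genes, 3 cytoskeleton genes and 6 unfolded protein response genes fell, while 2 oocyte transcripts and 1 unfolded protein response gene rose. The linker histone gene H1f8 fell 3.01-fold and Cnot6l 2.75-fold. With an estimated correlation the adjusted p was 0.583 for chromatin enzymes and 0.558 for the other 6 lists.

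Higher in LPN than in EPN were proteasome subunits (relative median 0.56, 1 of 37 rose, adjusted p = 0.000113), mitochondrial ribosomal proteins (0.55, 1 of 74, adjusted p = 2.16e-05), oxidative phosphorylation genes (0.48, 1 of 79, adjusted p = 8.2e-05) and cytosolic ribosomal proteins (0.39, no member of 89, adjusted p = 5.04e-05). DNA replication genes (0.34, 1 of 61, adjusted p = 0.0223), 2-cell-specific genes (0.29, no member of 40, adjusted p = 0.0349) and ribosome biogenesis genes (0.21, 1 of 100, adjusted p = 0.0349) were also called. Adjusted over the list alone, 4 proteasome, 4 ribosome biogenesis and 2 DNA replication genes rose, and 1 proteasome gene fell. Examples were Psmc5 (2.64-fold), Mrps30 (2.56-fold), Uqcr10 (2.74-fold) and the replication gene Gins1 (3.2-fold). With an estimated correlation the adjusted p was 0.615 for 2-cell genes, 0.589 for ribosome biogenesis and 0.558 for the other 5.

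Leaving out single libraries, which also leaves fewer samples, ended several of these list calls. For 2-cell genes the relative median was 0.22 without EPN A (adjusted p = 0.175), 0.33 without EPN C (0.161), 0.17 without LPN B (0.142) and 0.21 without LPN C (0.453). For ribosome biogenesis it was 0.02 without EPN A (adjusted p = 0.507) and 0.19 without LPN C (0.456). Without LPN C, oocyte-derived transcripts had a relative median of -0.10 (adjusted p = 0.0668) and DNA replication genes of 0.32 (0.0529). Preimplantation factors were at -0.31 without LPN A (adjusted p = 0.0965), and unfolded protein response genes at -0.18 without EPN A (0.108). Other settings ended calls too: for 2-cell genes no filter (0.20), quantile normalization (0.17) and array quality weights (0.13), for ribosome biogenesis quantile normalization (0.10) and weights (0.14), and for DNA replication quantile normalization (0.33). A mean of at least 5 CPM ended those of blastocyst markers (-0.57) and preimplantation factors (-0.21). The gene count was 19 without EPN A, 108 without EPN B, 13 without EPN C, 16 without LPN A and 4 without LPN B. It was 17 with edgeR, 1003 with DESeq2, 62 with a pseudocount of 0.1 CPM and 0 by limma with no filter (3015 at an unadjusted p under 0.05). The share of calls higher in LPN was 45.2% as deposited, 70.6% of 180 with median-of-ratios scaling and 55.1% of 247 with quantile normalization.

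The differences of EPN and LPN from SPN shared a direction in many genes. Calhm3, Ciart, Efna1, Ctsc, Srsf5 and Tdpoz8 were among 8 genes called higher in both, and Clint1 was the 1 gene called lower in both; no gene was called in opposite directions. Independent lists of these sizes would share 0.36 and 0.28 genes. Of the 1309 calls in LPN, 92.4% had an EPN difference of the same sign. Genes called higher in LPN had a median difference of 1.33 there and 0.58 in EPN, and genes called lower had -1.46 and -0.49. Since both comparisons use the same 3 SPN libraries, unchanged groups also share a direction. In 100 simulations, residuals from the group means were mixed, those of EPN and LPN together and those of SPN apart. This procedure was revised for faults of method after its output had been seen. A mean of 1.11 genes was called in both (range 0 to 111), and the same-sign share averaged 80.9% (range 0.8% to 100%). The observed 9 genes and 92.4% lay inside both ranges. These ranges are so wide that the simulation cannot tell a shared effect from the shared SPN libraries.

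**Figure D4:**
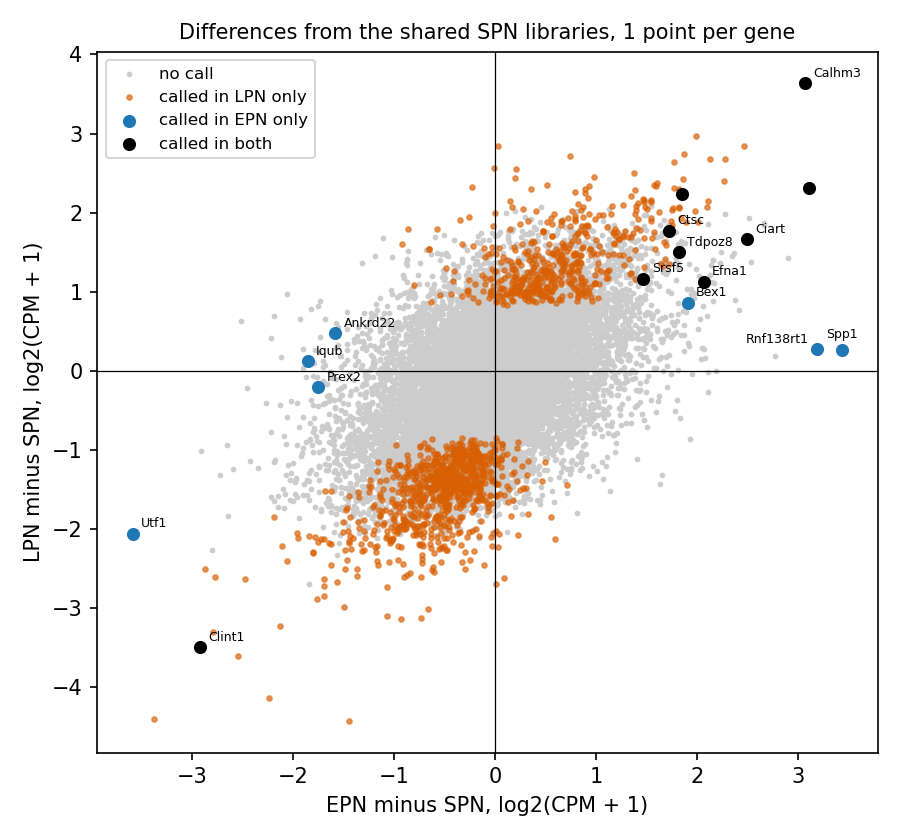
Log2 differences from SPN, EPN on the horizontal and LPN on the vertical axis, in log2(CPM + 1); each point is 1 of 14876 tested genes, coloured by call. Black points are the 9 genes called in both, and Spp1 and Iqub lie near 0 on the LPN axis.

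The overlap of 9 genes was 328 without SPN A, 1 without SPN B, 1 without SPN C, 3 without EPN A, 3 without EPN B and 0 by limma without EPN C; edgeR shared 0 and DESeq2 62. Iqub, Prex2 and Ankrd22, lower in EPN than in SPN, had LPN levels of 103 ± 36.6, 137 ± 34.9 and 122 ± 14.6 CPM.

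The lists of cumulus, sperm and blood cell markers had no call in any comparison. Summed CPM of the cumulus and granulosa markers was 818 ± 186 in SPN, 731 ± 207 in EPN and 867 ± 126 in LPN. Sperm markers summed to 154 ± 23.7, 109 ± 24.2 and 124 ± 15.3 CPM, and blood cell markers to 71.3 ± 33.0, 70.9 ± 26.3 and 34.0 ± 13.6 CPM (SD, n = 3; exact permutation p from 0.1 to 1 over the 9 pairs of groups). The blood gene Hba-a1 was lower in LPN than in SPN (60.8 ± 34.7 to 19.3 ± 9.0 CPM, limma adjusted p = 0.0247) and the sperm gene Odf2 as well (2.07-fold, adjusted p = 0.0499). Hba-a1 made up most of the blood sum in SPN. Odf2 held 115, 74.7 and 111 CPM of the sperm sums of 161, 127 and 173 CPM in SPN A, SPN B and SPN C. Tested cumulus markers had a mean log2 value of 2.36 in SPN A, so few members carried their sum of 1029 CPM. The sums therefore do not measure amounts of these cells. Interferon-stimulated genes had relative medians of 0.08, 0.19 and 0.01 in EPN against SPN, LPN against SPN and LPN against EPN, with no member called. Y-linked genes summed to 0.1 CPM in EPN A and to 54.1 to 168 CPM in the other libraries, with no call. EPN A thus held almost no Y-linked RNA. The sex of the pooled embryos was not modelled, so unequal sex composition of the pools may add to differences that rest on EPN A. Relative to the median of all genes, median, mean and test differed in sign only in lists without a call: DNA damage response and oxidative stress in EPN against SPN, mitochondrially encoded, heat shock and Y-linked genes in LPN against SPN, and apoptosis, interferon-stimulated and blood genes in LPN against EPN.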

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

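Tests chosen only after their result was seen were those of 1 deviating library, of LPN embryos further along normal development, and of an exchange of SPN A with EPN A, the calibration of the wrong-label test on LPN libraries, and the use of older symbols in the length and GC test, added because current symbols covered too few 2-cell genes for a valid test.

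The difference from SPN was unequal between EPN and LPN for 228 genes, tested directly by the limma contrast of LPN with EPN (edgeR 17, DESeq2 1003; 19 without EPN A, 108 without EPN B, 13 without EPN C, 16 without LPN A and 4 without LPN B). Tuba1c, Pou5f1 and Gpx1 were lower and Tefm and Parp2 higher in LPN, each in 3 of 3 libraries. LPN libraries had a mean of 5.12% of their reads outside the table, against 3.93% in SPN (exact permutation p = 0.1, the smallest possible) and 3.97% in EPN. What these reads belong to was not tested.

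In LPN against SPN, oocyte transcripts had a relative median of -0.52 (16 of 65 fell and 2 rose) and 2-cell-specific transcripts of 0.88 (11 of 40 rose), calls lost with an estimated correlation (adjusted p = 0.563 and 0.355 with an estimated correlation). Removing the trend on transcript length and GC left the oocyte list at -0.62 (interquartile range -1.15 to -0.32) and moved the 2-cell list from 0.8 to 0.7 (0.49 to 1.05) over the 80% of its genes covered, which argues against that trend as the whole cause. The gap between both lists was larger in LPN in 9 of 9 pairs of an LPN and an SPN library, so it did not rest on 1 library. It was not particular to LPN, since the EPN gaps (-0.13, 0.53 and -0.14) also lay above those of SPN (-0.54, -0.49 and -1.25). LPN A, at -0.1, lay near EPN A and EPN C. Embryos further along normal development could lose oocyte transcripts sooner. Later-stage markers had a relative median of -0.56 (camera p = 0.207 at an estimated correlation). These are blastocyst lineage markers, which cannot show a small lead among embryos taken at 34 h, so the value counts neither for nor against it. Stage and procedure cannot be told apart here. An effect of the transfer timing itself stays open as well, as do reads shared within the Eif1ad, Usp17l and Zscan4 families.

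More genes differed from SPN in LPN (1309) than in EPN (16). With every library thinned to 7611781 reads, LPN had at least 72.4 times as many calls in each of 5 draws, and leaving out any 1 library left a ratio of at least 6.01, reached without SPN A. Depth therefore does not account for the excess. LPN kept more calls than EPN whichever library was left out, but the size of the excess changed with single libraries. In EPN and LPN against SPN, 458 and 2753 genes were called without SPN A. The counts were 3 and 123 without SPN C, and 19 and 321 without LPN B. Where few genes were called in EPN, the ratio hardly tests the excess. Of the 10 splits of the 6 libraries in each comparison, 1, the real one, gave as many calls in EPN against SPN (16, highest other 10), in LPN against SPN (1309, highest other 11) and in LPN against EPN (228, highest other 1), and 10 splits are too few for a share under 0.05. For the F test 2 of 100 drawn splits of the 9 libraries, the real one among them, gave at least the real 852 genes. This share of 0.02 lies under 0.05. The highest other gave 1254 and was the split exchanging SPN A with EPN A. That points to a structure among the SPN and EPN libraries. Both of these splits kept the LPN libraries together, as did 1 with 104 genes, while splits that divided LPN gave at most 28. The share therefore argues against chance only for LPN apart from the other libraries, and gives no support to the SPN and EPN labels. Whether the pools share days, matings or operators is not known, so such a shared origin cannot be excluded either.

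SPN A resembled the EPN libraries more than SPN B and SPN C, with mean rank correlations of 0.916 with EPN, 0.897 with SPN and 0.896 with LPN. Thinning to equal depth left the lowest excess for EPN at 0.019 after rounding, which argues against depth. EPN A correlated more with EPN B and EPN C than with SPN B and SPN C, by 0.027, so it was not out of place, as an exchange of both A libraries would need; that exchange gave fewer calls in EPN against SPN (10 against 16) but more in the F test (1254 against 852). A wrong label of SPN A alone remains a candidate explanation: from 0 for SPN B and SPN C to 1 for EPN, it lay at 0.87 on 300 genes, inside the 0.84 to 0.96 of left-out EPN libraries. Scored on a scale of their own, with 0 for the other SPN libraries (SPN A included), SPN B and SPN C lay at 0.24 and 0.19, which sets SPN A apart within its group. LPN libraries lay at 0.87 to 1.05 on the scale of SPN A, so the position does not separate EPN from LPN, and with 3 SPN libraries a wrong label and an unusual SPN pool cannot be told apart.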

How the results depend on the processing

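No alternative was added after seeing the data. No called list or named gene reversed: over 28 called lists, 442 of 476 alternative results kept the call and 34 lost it, and over 149 called named genes 1955 of 2681 kept it and 726 lost it. Of 90 summed abundances, 80 moved by less than 1 SD under median-of-ratios scaling and 10 by more. The cause was not tested for the changes below, except that leaving out a library or fitting 6 libraries leaves fewer samples.

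In the order EPN against SPN, LPN against SPN, LPN against EPN, F test and overlap, limma called 16, 1309, 228, 852 and 9 genes. Array quality weights gave 313, 2731, 1321, 2891 and 184, with 7 lists called in EPN against SPN in place of 3. DESeq2 gave 142, 2012, 1003, 1862 and 62, and edgeR 0 (1342 at an unadjusted p under 0.05), 454, 17, 107 and 0. No filter gave 0 (1859 unadjusted), 494, 0 (3015 unadjusted), 0 and 0 with limma, over 19189 genes. A pseudocount of 0.1 CPM gave 4, 1041, 62, 546 and 2. Median-of-ratios scaling gave 3 genes in EPN against SPN and an overlap of 3, a mean of at least 5 CPM gave 395 in LPN against EPN, and fits of only the 6 libraries of the pair gave 772 in LPN against SPN and 588 in LPN against EPN.

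With a replicate block for the letters A, B and C the counts were 25 in EPN against SPN, 480 in LPN against EPN and 15 in the overlap; correlations of same-letter deviations ran from -0.02 to 0.09, while 6 of 9 libraries correlated best, outside their group, with one of the same letter. Nothing in the labels says that the letters pair libraries, and these values leave it open. Leaving out 1 library gave 0 (EPN C) to 458 (SPN A) genes in EPN against SPN, 123 (SPN C) to 2753 (SPN A) in LPN against SPN, 4 (LPN B) to 288 (LPN C) in LPN against EPN, 63 (LPN B) to 2565 (SPN A) in the F test and 0 (EPN C) to 328 (SPN A) in the overlap, and 1 (SPN C) to 9 (SPN A, EPN B) lists in EPN against SPN. Depth of 7611781 to 15559218 reads put 3 reads at 0.193 to 0.394 CPM, so differences under those levels were not detectable.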

Other observations

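The family test below was chosen after the data were seen. Among 1332 tests of genes sharing a symbol stem, the smallest p was that of Zfp-named zinc finger genes, for genes higher in LPN than in SPN. Of these 333 genes 35 rose and 9 fell (Fisher's exact test, adjusted p = 1.36e-06), and 38 rose and 5 fell with median-of-ratios scaling. Their relative median was 0.22 (camera p = 0.00175, and p = 0.0151 with an estimated correlation, neither adjusted over the families). This is no independent evidence, since the family was picked on the same values. Eif-named genes, Eif1ad copies among them, had 12 of 64 higher (adjusted p = 0.000589) and Psmd-named genes 5 of 14 (adjusted p = 0.0251). Both are larger shares than that of the Zfp-named genes. Fisher's exact test treats genes as independent, although Eif1ad copies can share reads. Zfp809 rose by 1.58 and Zfp977 by 1.89 on the log2 scale, both chosen after their values were seen.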
